A study of Mus musculus with 6 samples.

How the data were processed

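Total RNA from frozen, powdered mouse quadriceps was depleted of ribosomal RNA and sequenced from a stranded total RNA kit, with 3 libraries from floxed controls and 3 from mice that also carry the MCK-Cre transgene. Per the submitters' processing notes, the authors trimmed reads with cutadapt 1.9.3, aligned them with HISAT2 2.0.4 to build mm10 and quantified genes with Cufflinks and Cuffdiff, whose versions are not given in the sources used here. The deposited table holds 22564 protein-coding genes by Ensembl identifier, and 1 line of it was emptied for this work. It has 1 column per library of FPKM, fragments normalised by the authors to gene length and sequencing depth. How the authors scaled the FPKM values between libraries is not stated, nor whether counting used the strand, so signal from overlapping genes on the opposite strand cannot be set apart.

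The deposited table also holds columns that the authors headed as counts. Each is a scaled signal per library, in which estimated fragments per gene were multiplied by 1 constant. Between 92.6% and 94.2% of the values above 0 were whole multiples of that constant within a tolerance of 0.1, too few to recover whole fragments, so no count test was run. Divided by the constant, the column totals give 8435736 to 11783863 estimated fragments per control library and 3150440 to 6704239 per knockout library. Among pairs of replicates, the squared differences between estimated fragments came to between 1.84 and 8.53 times what sampling of fragments alone gives, a spread that also holds differences between samples.

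Rows that share a symbol were summed, which affected 79 of 22481 symbols. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 11659 in all. The log2 values, with a pseudocount of 0.1 FPKM, were compared between knockout and control with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with a mean-variance trend), and p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Fbxw7 alone was also compared with an exact two-sided permutation test. The p-values measure the spread between these samples, as the labels do not state that each library is a separate animal. Positions are from GENCODE M21 on mm10, matched by Ensembl identifier.

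Lists of genes for fuel use, fibre type, muscle growth and loss, stress responses and the cell types of muscle, 51 in all, were compared with the other genes by camera from limma with a preset correlation of 0.01. The 49 lists with at least 5 tested members were adjusted together. Camera with an estimated correlation and fry, which tests whether a list moves on balance without comparing it with other genes, were run beside it. The lists, the test, its thresholds and the rule for naming genes were chosen before the data were examined. By that rule the text names Fbxw7, the 12 raised and 12 lowered genes with the largest change among called genes whose 3 knockout values all lie on one side of the 3 control values and whose higher mean is at least 1 FPKM (predicted and unnamed genes left out), up to 4 members with the smallest p in each list described, and any gene that an alternative setting is about. Some genes that the rule picks are not reported here. Other genes are said to have been chosen after their values were seen. A further 5 lists and the pathway labels that the table carries (273 with 10 to 300 tested genes) were examined for the closing part. The 5 lists were adjusted together by themselves, and so were the 273 labels.

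In 1 simulated data set made from the 6 libraries with 100 genes changed at each size, the test recovered 75% of genes changed by 1 on the log2 scale and 93% of those changed by 2, and 7.18% of its calls were false. It held 11534 genes, none listed at 0, with noise drawn separately per gene and no general shift between groups. In the real data 34.6% of genes were called, so these rates need not carry over. Alternatives covered the pseudocount, the filter, scaling between libraries, the form of the limma fit, a block by replicate number, the threshold, leaving out each library in turn and, chosen after seeing the data, the scaled count columns and leaving out genes listed at 0 in any library. As deposited, 125 tested genes are listed at 0 in at least 1 library, and the 9 of these with a mean of 10 FPKM or more are all mitochondrially encoded. No fold is given against a group listed at 0 throughout.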

Results

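The series asks what loss of FBXW7 changes in skeletal muscle, in connection with glucose use after feeding and the upkeep of muscle mass. FBXW7 is the F-box subunit by which a ubiquitin ligase recognises its substrates. Quadriceps transcripts were measured in 3 libraries from mice homozygous for a floxed Fbxw7 allele and 3 from mice of the same genotype with Cre under the muscle creatine kinase promoter, which deletes the floxed sequence in muscle. The control mice carry no Cre, so the presence of Cre and the loss of Fbxw7 go together. Estimated fragments numbered 11242812, 11783863 and 8435736 in the control libraries and 3150440, 6704239 and 6128449 in the knockout libraries. At 1 FPKM, a level already scaled for depth, 10508 to 10588 genes were reached in the knockout libraries, against 9743 to 10030 in the controls. Rows above 0 in the scaled count columns numbered 14289 to 15190 in the knockouts and 14659 to 15039 in the controls. All values below are mean FPKM ± SD with n = 3 per group unless stated otherwise, and adjusted p-values are from limma.

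Knockout quadriceps held less Fbxw7 transcript. In the lists fixed beforehand, most tested fast fibre and glycolysis genes fell, as did 10 of 22 glycogen genes. Most tested genes of fatty acid use and protein folding rose. Camera called these 5 lists, with adjusted p between 0.170 and 0.479 for each with an estimated correlation. Fbxw7 (ENSMUSG00000028086, chromosome 3, 84815268 to 84979198, plus strand) averaged 6.37 ± 0.141 in controls and 3.90 ± 0.113 in knockouts, a log2 change of -0.69 (SE 0.12, adjusted p = 0.0028). The 3 control libraries read 6.51, 6.23 and 6.36 and the 3 knockout libraries 4.02, 3.86 and 3.81. An exact two-sided permutation test of this gene alone gave p = 0.1, the smallest value that 3 libraries against 3 allow. A floxed allele loses only part of the gene, and exons that remain, like other cell types in the tissue, still contribute to a value summed over the gene.

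Across the transcriptome 4037 of 11659 tested genes differed (34.6%), with 2860 raised and 1177 lowered in the knockout. Changes of at least 2-fold were seen in 834 raised and 276 lowered genes. The first principal component held 56.1% of the variance, and 49.8% of tested genes had all 3 knockout values on one side of all 3 control values, where chance gives 10%. The median log2 change of all tested genes was 0.21. It was 0.01 under median-of-ratios scaling, which gave 1724 raised and 2018 lowered genes, and close to 0 under quantile normalization, with 1715 raised and 1696 lowered. Both scalings centre the typical gene by construction. The balance of raised and lowered genes thus changes with the scaling, and these counts do not decide which balance is right. List medians are therefore also given relative to the median of all tested genes.

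Among the strongest increases outside immune genes were those of Uchl1, a ubiquitin hydrolase abundant in neurons, and Sln, which encodes sarcolipin, a small inhibitor of the calcium pump of the sarcoplasmic reticulum. Uchl1 (ENSMUSG00000029223, chromosome 5, 66676091 to 66687234) rose 45.6-fold, from 5.85 ± 0.895 to 267 ± 23.9 (log2 5.49, SE 0.12, adjusted p = 8.75e-08). Sln (ENSMUSG00000042045, chromosome 9, 53850164 to 53854560) rose 23.9-fold, from 6.69 ± 0.353 to 160 ± 10.1 (log2 4.56, SE 0.09, adjusted p = 3.06e-08). Fam171b rose 28.7-fold, from 0.510 ± 0.167 to 14.6 ± 0.853. The other 9 of the 12 most raised genes belong to immune cells or the vessels of lymphoid tissue. Of these, Iglc2, Cd79a, Glycam1, Marco and Faim3 were listed at 0 in every control library, and their knockout values lay between 1.91 for Faim3 and 8.69 for Iglc2. Lck, Ms4a4b, Ptprcap and Ltb were listed at 0 in 2 of the 3 control libraries and averaged between 3.24 for Ltb and 3.94 for Ms4a4b in the knockouts.

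Among the 12 most lowered genes, Mss51, whose product associates with mitochondria in muscle (ENSMUSG00000021815, chromosome 14, 20482867 to 20496901), was 44.1-fold lower, at 79.3 ± 0.784 in controls and 1.80 ± 0.685 in knockouts (log2 -5.45, SE 0.22, adjusted p = 1.63e-06). Amd1, the S-adenosylmethionine decarboxylase that supplies the aminopropyl groups of spermidine and spermine, was 17.2-fold lower, at 634 ± 26.8 and 36.9 ± 2.65. Smox, the oxidase that converts spermine back to spermidine, was 16.1-fold lower, at 444 ± 26.5 and 27.6 ± 3.80. Ostn, which encodes the secreted peptide musclin, was 18.7-fold lower, at 50.2 ± 1.76 and 2.69 ± 0.446. Odf3l2 was 34.7-fold lower, at 32.2 ± 2.32 and 0.926 ± 0.617. Fgfbp1, a carrier of fibroblast growth factors, averaged 4.995 ± 1.001 and 0.0659 ± 0.114, and Cthrc1, Tsga10ip and Gdpd3 fell from between 3.70 and 4.90 to 0.129, 0.130 and 0.165. Values for Amd2 (15.4 ± 1.83 and 1.11 ± 0.208), Mup7 (2.03 ± 1.29, listed at 0 in the knockouts) and Rpl41 (125 ± 0.511 and 9.57 ± 4.62) are uncertain, since the first 2 have near-identical relatives and Rpl41 is very short.

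**Figure D1:**
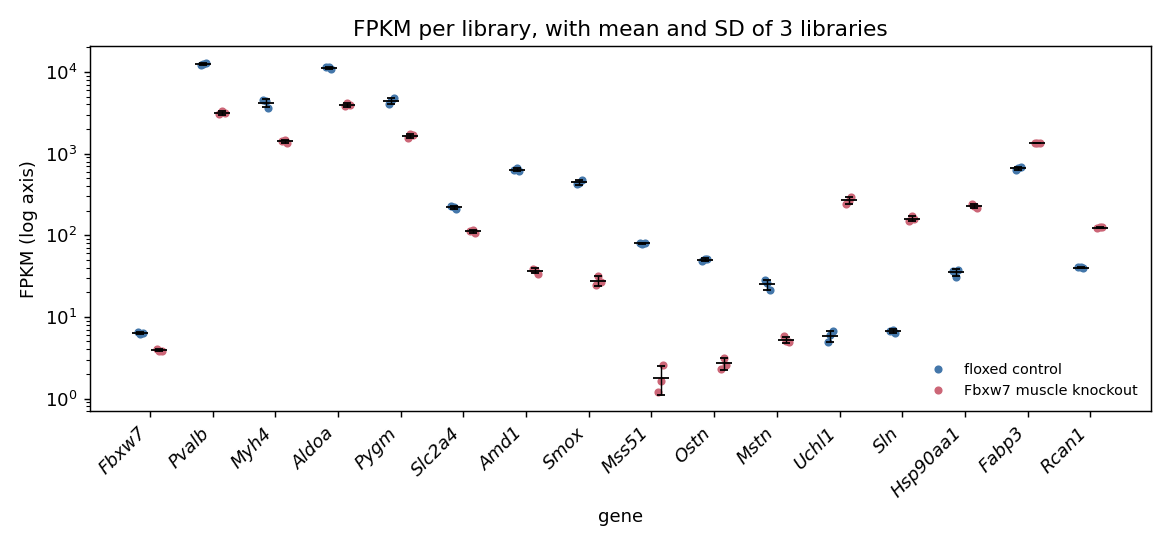
FPKM on a log axis for 16 genes in the 3 floxed control libraries (blue) and the 3 Fbxw7 muscle knockout libraries (red), each point 1 library, with the mean and SD of the group in black. Fbxw7 averaged 6.37 in controls and 3.90 in knockouts, while Uchl1 rose from 5.85 to 267 and Mss51 fell from 79.3 to 1.80.

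Genes of fast, glycolytic fibres fell together. Of 19 fast fibre genes, 16 fell and 2 rose (16 and 3 when adjusted over the list alone), with a median log2 change of -1.36, or -1.57 relative to all tested genes (camera adjusted p = 2.82e-17, adjusted p = 0.170 with an estimated correlation). Pvalb, the calcium buffer parvalbumin of fast fibres, fell from 12570 ± 329 to 3175 ± 177, the troponin gene Tnni2 from 8994 ± 262 to 2794 ± 110, and the tropomyosin gene Tpm1 from 20120 ± 973 to 6470 ± 175. The fast myosin light chain gene Mylpf fell from 13180 ± 564 to 4995 ± 65.0, though its call ended under quantile normalization (log2 -0.48, adjusted p = 0.0948). Among myosin heavy chains, chosen after their values were seen, Myh4 of type IIb fibres fell from 4186 ± 496 to 1416 ± 54.2, while Myh1 of type IIx rose from 187 ± 18.9 to 408 ± 10.6 and Myh2 of type IIa from 148 ± 9.77 to 232 ± 2.47. Fast fibre genes took 27.2% to 28.4% of the nuclear-encoded FPKM in controls and 14.3% to 14.6% in knockouts. Of 18 slow fibre genes, 5 rose and 6 fell (7 and 6 adjusted over the list alone), and the list was not called (median 0.08, camera adjusted p = 0.704). Within it Sln, the calcium-binding Casq2 (10.5 ± 0.790 to 28.8 ± 0.836) and the pump inhibitor Pln (0.763 ± 0.0936 to 4.02 ± 0.430) rose, and the slow troponin Tnnt1 fell (95.3 ± 3.76 to 49.5 ± 4.63).

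Most genes of the glycolysis list fell in the same libraries, and fewer of the glycogen genes did. The wider pathway label Glycolysis / Gluconeogenesis, examined after the results were seen, was not called. Of its 47 genes 11 rose and 15 fell (median 0.06, camera adjusted p = 0.0547). Of 25 glycolysis genes, 16 fell and 5 rose, also when adjusted over the list alone, with a median of -0.78, or -0.98 relative to all tested genes (camera adjusted p = 6.25e-09, adjusted p = 0.407 with an estimated correlation). Aldolase A (Aldoa) fell from 11160 ± 381 to 3970 ± 195, although its call ended under quantile normalization (log2 -0.62, adjusted p = 0.12). Lactate dehydrogenase A (Ldha) fell from 1667 ± 91.6 to 651 ± 10.5, the muscle fructose bisphosphatase Fbp2 from 37.4 ± 3.01 to 4.71 ± 0.799, and Pfkfb3, which makes the activator of phosphofructokinase, from 56.3 ± 3.33 to 8.68 ± 0.647. The 5 that rose, named after their values were seen, were Pfkfb2, Pfkl, Ldhb, Slc16a1 and Pgam1, and Ldhb was not called under median-of-ratios scaling (log2 0.16, adjusted p = 0.0927). Of 22 glycogen genes, 10 fell and 2 rose (10 and 4 adjusted over the list alone), with a median of -0.11, or -0.32 relative to all tested genes (camera adjusted p = 1.59e-04, adjusted p = 0.407 with an estimated correlation). Muscle glycogen phosphorylase (Pygm) fell from 4421 ± 352 to 1650 ± 101, its activating kinase subunits Phkg1 and Phka1 from 206 ± 7.01 to 68.1 ± 4.78 and from 152 ± 15.5 to 46.6 ± 2.29, and Pgm2 from 568 ± 27.5 to 193 ± 6.57. The 2 that rose, named after their values were seen, were Stbd1 and the branching enzyme gene Gbe1.

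Genes for the entry of glucose went both ways. Of 24 genes of glucose uptake and insulin signalling, 6 rose and 5 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.258). The median was 0.11 and turned to -0.09 under median-of-ratios scaling (4 raised, 9 lowered) and -0.14 under quantile normalization (5 raised, 8 lowered). The insulin-responsive transporter Slc2a4 fell from 219 ± 10.3 to 112 ± 4.17 (log2 -0.97, SE 0.06, adjusted p = 1.82e-05) and hexokinase 2 (Hk2) from 58.9 ± 3.02 to 37.9 ± 1.03. Txnip, an inhibitor of glucose uptake, fell from 297 ± 18.9 to 133 ± 4.68.

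Fatty acid genes rose. Of 36 genes of fatty acid uptake and oxidation, 27 rose and 1 fell (28 and 1 adjusted over the list alone), with a median of 0.54, or 0.33 relative to all tested genes (camera adjusted p = 4.91e-06, adjusted p = 0.479 with an estimated correlation). Under median-of-ratios scaling 20 rose and 4 fell. The fatty acid binding protein Fabp3 rose from 664 ± 26.9 to 1348 ± 16.7, lipoprotein lipase (Lpl) from 47.8 ± 5.95 to 108 ± 7.73, the dehydrogenase Acadl from 121 ± 4.67 to 210 ± 7.22 and the triglyceride lipase Pnpla2 from 105 ± 2.43 to 186 ± 13.8. The 1 that fell, named after its values were seen, was Ucp3 (44.1 ± 5.77 to 34.8 ± 0.479). Its call ended without a filter, without the limma trend and on leaving out any library other than control 3 (adjusted p 0.0595 to 0.12). Adipocyte markers moved in the same direction, with 11 of 16 raised and 1 lowered (12 and 1 adjusted over the list alone), a median of 0.93, or 0.72 relative to all tested genes, and camera adjusted p = 0.0259 (adjusted p = 0.764 with an estimated correlation). Cfd rose from 51.7 ± 3.84 to 117 ± 2.25, Pck1 from 1.39 ± 0.105 to 5.09 ± 0.319 and Cidec from 3.84 ± 0.284 to 9.51 ± 0.719, while Car3, abundant in fat and in slow muscle, fell from 941 ± 67.0 to 514 ± 33.2. The adipocyte call ended with a filter at a mean of 2 FPKM (adjusted p = 0.0731).

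Nuclear genes of the respiratory chain gave no single direction. Of 48 respiratory chain genes, 7 rose and 12 fell (the same counts when adjusted over the list alone, camera adjusted p = 0.0757), with a median of 0.01, a mean of -0.01 and a camera direction of down. The direction depended on the scaling, with 1 raised and 22 lowered under median-of-ratios scaling (camera adjusted p = 4.80e-05) and 15 raised and 2 lowered under quantile normalization (adjusted p = 0.0539). Leaving out control 1 or control 2 also gave a call downward (adjusted p = 0.0245 and 0.0482). Values of mitochondrially encoded mRNAs, a list that was not called (adjusted p = 0.489), are not usable for a comparison, since mt-Co1 for example was listed at 0 in all control libraries and knockout 2 but at 57590 and 52400 in knockouts 1 and 3.

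Protein folding genes rose. Of 20 heat shock and folding genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.67, or 0.46 relative to all tested genes (camera adjusted p = 4.06e-05, adjusted p = 0.407 with an estimated correlation). The chaperone Hsp90aa1 rose from 35.0 ± 3.55 to 227 ± 11.6, the small heat shock genes Hspb7 from 136 ± 3.53 to 495 ± 49.4 and Hspb1 from 158 ± 10.9 to 485 ± 29.5, and the co-chaperone Bag3 from 54.5 ± 1.95 to 174 ± 16.1. The 2 that fell, named after their values were seen, were Dnajb5 (102 ± 3.19 to 57.0 ± 1.55) and Hspb2 (98.6 ± 9.11 to 82.5 ± 3.73). The call of Hspb2 ended in 8 of 19 alternatives, namely quantile normalization (log2 -0.15, adjusted p = 0.196), the replicate block, no filter, no limma trend, and without control 2, control 3, knockout 2 or knockout 3 (adjusted p 0.056 to 0.148). Cytosolic ribosomal protein genes fell by a small amount, 34 of 56 with 2 raised (39 and 2 adjusted over the list alone), with a median of -0.28, or -0.49 relative to all tested genes (camera adjusted p = 2.32e-16, adjusted p = 0.170 with an estimated correlation). The size depended on the scaling, with 48 lowered under median-of-ratios scaling (median -0.48) and 20 under quantile normalization (median -0.18). Rpl4 fell from 471 ± 4.62 to 308 ± 9.11 and Rps14 from 350 ± 10.4 to 246 ± 11.9. Rpl3, which muscle replaces in part by a paralog, rose from 28.4 ± 1.40 to 50.8 ± 1.54, and Rps19, named after its values were seen, from 99.8 ± 8.62 to 119 ± 1.61. The call of Rps19 ended in 9 of 19, namely median-of-ratios scaling (log2 0.05, adjusted p = 0.747), the scaled count columns, no filter, no limma trend and leaving out any library other than control 3 (adjusted p 0.0514 to 0.118).

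**Figure D2:**
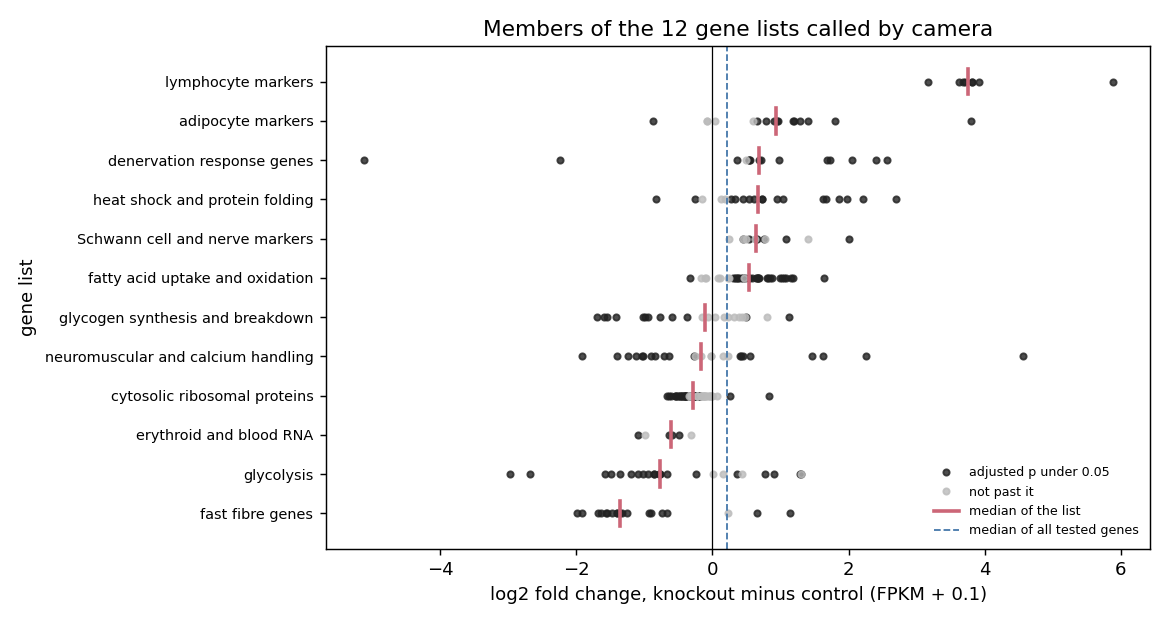
Log2 change (knockout minus control) of each tested member of the 12 gene lists called by camera, with members past an adjusted p of 0.05 in black, others in grey and the list median as a red bar. The blue dashed line marks the median of all tested genes, 0.21, and the lists run from fast fibre genes (median -1.36) to lymphocyte markers (median 3.76).

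Genes tied to muscle mass did not move as a group. Of 33 atrophy genes, 13 rose and 7 fell (14 and 7 adjusted over the list alone, median 0.24, camera adjusted p = 0.999), but 11 rose and 11 fell under median-of-ratios scaling (median 0.04) and 12 and 8 under quantile normalization (median 0.15). The ubiquitin ligase genes Trim63 and Asb2 fell, from 107 ± 5.30 to 42.4 ± 1.72 and from 252 ± 18.4 to 90.6 ± 12.2. The autophagy gene Map1lc3a rose (148 ± 2.92 to 245 ± 11.7). Of 26 regulators of growth and mass, 6 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.308). Myostatin (Mstn), which restrains muscle growth, fell from 25.0 ± 3.45 to 5.28 ± 0.451 (log2 -2.22, SE 0.13, adjusted p = 1.10e-05), and the orphan receptor Nr4a1 from 64.1 ± 3.84 to 30.5 ± 3.83. Gdf5, a bone morphogenetic protein, rose from 0.0539 ± 0.0330 to 1.32 ± 0.0984. The medians of these lists, of slow fibre genes and of glucose uptake genes were above 0 while camera, which sets a list against the other genes, pointed down. The growth median turned to -0.14 under median-of-ratios scaling and -0.18 under quantile normalization, with 3 and 2 raised and 6 and 7 lowered. The slow fibre median turned to -0.13 under the former (3 raised, 7 lowered) but was 0.14 under the latter (8 raised, 5 lowered).

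Genes of the response to denervation rose, with 12 of 15 raised and 2 lowered, also when adjusted over the list alone, and a median of 0.68, or 0.47 relative to all tested genes (camera adjusted p = 0.0176, adjusted p = 0.531 with an estimated correlation). Under median-of-ratios scaling and under quantile normalization 9 rose and 2 fell (medians 0.479 and 0.485). The stretch-responsive Ankrd1 rose from 14.4 ± 0.935 to 85.8 ± 4.62 and Arpp21 from 1.81 ± 0.151 to 6.26 ± 0.770, while Fgfbp1 and embryonic myosin (Myh3, 4.201 ± 0.490 to 0.821 ± 0.174) fell. Markers of Schwann cells and nerve moved with them, with 7 of 13 raised and none lowered (8 adjusted over the list alone), a median of 0.64, or 0.43 relative to all tested genes, and camera adjusted p = 0.0162 (adjusted p = 0.407 with an estimated correlation). Of the 13, 5 rose under median-of-ratios scaling and 4 under quantile normalization (medians 0.43 and 0.38). The myelin gene Mbp rose from 19.8 ± 2.003 to 30.7 ± 1.69. Both calls ended with a filter at a mean of 2 FPKM (adjusted p = 0.0745 for denervation and 0.0581 for Schwann cells). Of 25 genes of calcium handling and excitation, 8 rose and 11 fell, also when adjusted over the list alone, with Sln and the calcineurin regulator Rcan1 (40.2 ± 0.344 to 124 ± 2.17) raised and Casq1 (2389 ± 174 to 632 ± 58.2) and the calcium channel subunit Cacng1 (184 ± 13.2 to 77.7 ± 2.31) lowered. Camera called this list downward (adjusted p = 0.0162, adjusted p = 0.764 with an estimated correlation), its median was -0.17, its mean 0.02, fry pointed upward, and the call ended under quantile normalization (adjusted p = 0.42).

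Transcripts of genes whose proteins FBXW7 is known to bind were not called as a list by camera. Of 28, 7 rose and 3 fell, also when adjusted over the list alone (median 0.19, camera adjusted p = 0.747), but 5 rose and 6 fell under median-of-ratios scaling (median -0.01) and 5 and 5 under quantile normalization (median 0.06). Fry, which tests the list by itself, called it upward (adjusted p = 0.0472), but the list median was -0.0155 relative to all tested genes. Nfe2l1, which controls proteasome genes, rose from 125 ± 10.2 to 287 ± 3.27, the clock repressor Cry2 from 6.62 ± 0.879 to 14.3 ± 1.30 and Nfil3 from 8.82 ± 0.0987 to 14.7 ± 0.212, and the mitotic kinase Aurka fell from 9.64 ± 2.35 to 1.67 ± 0.392. None of the 11 tested Notch target genes was called by limma, nor when adjusted over the list alone (1 at an unadjusted p under 0.05, camera adjusted p = 0.638, fry adjusted p = 0.47). Some were called in alternatives: Lfng upward without the limma trend, with array weights, on the scaled count columns and without knockout 1 (adjusted p = 0.0495, 0.0315, 0.0394 and 0.0367), Notch1 upward without control 1 (adjusted p = 0.0388) and Hey1 downward under quantile normalization (adjusted p = 0.0361). Of the 11, 1 fell under median-of-ratios scaling.

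Markers of cells other than muscle fibres also differed between the groups. Of 17 lymphocyte markers, 8 passed the filter. All 8 rose, also when adjusted over the list alone, with a median of 3.76, or 3.55 relative to all tested genes (camera adjusted p = 3.43e-05, adjusted p = 0.170 with an estimated correlation). Markers near 0 in controls pass a filter on the mean of all 6 libraries only when high in knockouts. The filter therefore shaped this count, the median and these p-values. The median depends on the pseudocount, at 1.36 with 1 FPKM and 6.22 with 0.01 FPKM, since 3 of the 8 were listed at 0 in every control library. The B cell genes Cd79a and Cd79b averaged 5.87 ± 0.904 and 2.87 ± 0.745 in knockouts, against 0 in every control library for Cd79a and 0.125 ± 0.0538 for Cd79b. Of 18 macrophage and monocyte markers, 5 rose and none fell (4 adjusted over the list alone, camera adjusted p = 0.308), but 2 rose and 1 fell under median-of-ratios scaling and 3 and 1 under quantile normalization, with Cd74 at 60.5 ± 4.10 and 107 ± 13.8. Of 6 blood genes, 4 fell and none rose (5 lowered adjusted over the list alone), with a median of -0.62, or -0.82 relative to all tested genes (camera adjusted p = 2.11e-04, adjusted p = 0.407 with an estimated correlation). Bpgm fell from 57.6 ± 4.87 to 27.0 ± 0.748 and Hbb-bs from 183 ± 19.1 to 129 ± 13.4, although globin genes are near-identical and their separate values are uncertain. Of 17 endothelial markers 1 rose and 1 fell (1 and 0 adjusted over the list alone, median 0.08, camera adjusted p = 0.776), but none rose and 4 fell under median-of-ratios scaling (median -0.13) and 2 and 2 under quantile normalization (median -0.09). Of 14 smooth muscle markers none rose and 2 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.11), and 4 fell under either other scaling (adjusted p = 0.071 under median-of-ratios scaling and 0.0481 under quantile normalization).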

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

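The scaled count columns and the removal of genes listed at 0 were chosen after seeing the data, the other alternatives before. The fall of Fbxw7 stayed past the threshold in all 19 alternatives run on it (log2 -0.96 to -0.59). Over all alternatives between 3020 and 5156 genes were called, the latter at an adjusted p under 0.1. At the threshold of 0.05 the highest count was 4924, on the scaled count columns. Raised genes dropped from 2860 to 1724 under median-of-ratios scaling and 1715 under quantile normalization, and lowered genes came to 2018 under the former. By construction these scalings centre the change of the typical gene, and 2901 and 2728 of the 4037 calls were shared. Blocking by replicate number, where the libraries of a block share only that number, gave 3828 calls, 3608 of them shared. Of the 49 lists, camera called 12 as reported and 0 with an estimated correlation (4 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 31. The 12 were all called again in 17 of the other 20 alternatives. Of the 12, 11 were called under quantile normalization and 8 with a filter at a mean of 2 FPKM, where 3 lost their call. Without the genes listed at 0, 11 were called. Under that filter and without the genes listed at 0, the lymphocyte list had too few members to test and gave no value. Quantile normalization turned mt-Nd2 from 0.26 to -0.46 (adjusted p = 0.278), and leaving out 1 library gave Gapdh values from -0.96 (without control 1) to 0.50, against 0.003 with all. Gapdh read 580 in control 1 against 4194 and 4375 in the other controls, and it was chosen after its values were seen. The cause of the other changes of call was not tested. Leaving out each library in turn gave 3020 to 3933 changed genes, 2019 to 2830 raised and 815 to 1103 lowered. An edgeR or DESeq2 count test was planned and not run, as whole fragments could not be recovered. Depth limits low values, with 3150440 estimated fragments in knockout 1 against 11783863 in control 2.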

Other observations

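The polyamine, B cell, T cell and lymph node lists, the pathway labels, the scaling tests of lymphocyte and fast fibre genes, the lymphoid tissue test and the fast fibre share test were chosen only after the results were seen. So were the conditions that leave scaling and depth open as causes of the excess of raised genes, for which 46.1% and 54.9% met the bound of 55% set beforehand in their favour. The polyamine list (Amd1, Amd2, Smox), the B cell list (Iglc2, Cd79a, Faim3), the T cell list (Lck, Ms4a4b, Ltb) and the lymph node list (Glycam1) hold the genes that prompted them, so their counts and p-values are not independent evidence. Of 15 polyamine genes, 5 fell and 4 rose (median log2 -0.14, camera adjusted p = 0.00704, adjusted p = 0.169 with an estimated correlation), but 2 rose and 6 fell under median-of-ratios scaling (median -0.34) and 4 and 6 under quantile normalization (median -0.37). Of the 4 raised, Sms and Sat1 each lost their call in 10 of 19 alternatives (adjusted p up to 0.901 and 0.282). Ornithine decarboxylase (Odc1), the entry enzyme, fell from 95.5 ± 10.3 to 61.5 ± 2.63 FPKM (SD, n = 3), and its inhibitor antizyme 1 (Oaz1) fell from 361 ± 19.4 to 241 ± 8.60. Azin1, which binds antizyme, rose from 9.87 ± 0.882 to 26.5 ± 5.29, and Sat2 rose from 4.36 ± 0.723 to 8.60 ± 0.981.

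Other lists fixed beforehand were not called by camera but held called members. Of 22 unfolded protein response genes, 12 rose and 1 fell, also when adjusted over the list alone (median 0.49, camera adjusted p = 0.0507), but 7 rose and 2 fell under median-of-ratios scaling (median 0.29) and 6 and 1 under quantile normalization (median 0.31). The list was called without control 2 (adjusted p = 0.0353), without knockout 2 (adjusted p = 0.0483), under quantile normalization (adjusted p = 0.0265), with no filter (adjusted p = 0.0155), with a pseudocount of 0.01 (adjusted p = 0.0472) and by fry (adjusted p = 0.00468). Hsp90b1 rose from 38.4 ± 0.640 to 55.6 ± 3.27 FPKM and Calr from 65.3 ± 2.39 to 89.4 ± 1.07. Of 19 citrate cycle genes, 9 rose and none fell (10 adjusted over the list alone, camera adjusted p = 0.0771), but under median-of-ratios scaling 6 rose and 4 fell (adjusted p = 0.594) and under quantile normalization 12 rose (adjusted p = 3.64e-05). This list was also called with no filter (adjusted p = 0.0392), with the replicate block (adjusted p = 0.0481) and by fry (adjusted p = 0.0105). Mdh1 rose from 381 ± 25.3 to 595 ± 34.9. Of 20 glucocorticoid response genes, 7 rose and 7 fell, also when adjusted over the list alone (camera downward, adjusted p = 0.41, median 0.16 and -0.04 under median-of-ratios scaling), with Sgk1 and Tsc22d3 lowered from 85.9 ± 6.78 to 41.2 ± 2.68 and from 109 ± 9.21 to 62.5 ± 1.27. Of 23 matrix and fibroblast genes, 11 rose and 3 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.264, fry adjusted p = 0.0472), among them periostin (Postn), which fell from 67.9 ± 6.80 to 16.9 ± 1.86. Among the 273 pathway labels, 13 were called upward and 6 downward by camera and none with an estimated correlation (adjusted p = 0.998 for each). Antigen processing and presentation had 37 of 53 genes raised and 1 lowered, and 27 raised and 1 lowered under median-of-ratios scaling.

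The 8 lymphocyte genes were near or at 0 in all controls and present in all 3 knockout libraries, with 8 of 8 B cell genes raised (median log2 4.09, adjusted p = 0.0295 with an estimated correlation) and 8 of 10 T cell genes (median 3.75, adjusted p = 0.0576 with an estimated correlation), of which the lymphocyte list holds 4 and 4. Genes near 0 in controls pass the filter only when high in knockouts, so the filter also shaped these counts, medians and p-values. The lymphocyte list lay 3.55 above the median of all genes. The filter and the pseudocount shaped that value too (the list median was 1.36 with a pseudocount of 1 FPKM), so it does not decide on scaling between libraries. Lymphoid tissue carried along with the muscle may contribute, since the median of 7 lymph node stroma and venule genes was 1.15, with Ccl19 at 0.303 and 4.36, Cxcl13 at 0.986 and 5.84 and Ccl21a at 7.30 and 16.2 FPKM in controls and knockouts. Pdpn (3.38 and 3.26) and Cd34 (26.3 and 24.3) were not called and as high in controls (Cd34 was lowered under median-of-ratios scaling, log2 -0.31, adjusted p = 0.0139), and while 1.15 lies between the bounds set for and against, the 0.95 and 0.97 under median-of-ratios scaling and quantile normalization lie just under the bound against. Inflammatory infiltration also stays open, as the higher of the macrophage and cytokine medians was 0.588, although it was 0.394 and 0.256 under the same scalings, below the bound of 0.5 set against it, and a response to the loss of Fbxw7 was not tested.

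More genes were raised than lowered, and the technical explanations weighed here stay open. Raised genes made up 46.1% of calls under median-of-ratios scaling, against 70.8% as reported, but that scaling centres the typical gene by construction, so the value does not decide whether scaling could be the cause. Lower depth of the knockout libraries stays open as well, since 54.9% of the 1832 calls at a mean of 10 FPKM or more were raised, against 84.1% of the 2205 calls below it, but 29.5% of those at the higher level were under median-of-ratios scaling. A smaller share of signal in fast fibre genes stays open as a contribution. Leaving them and the mitochondrially encoded genes out of the library totals gave a median of 0.373, against 0.608 with only the mitochondrially encoded ones left out. The difference of 0.235 exceeds the reported shift of 0.21, but that shift was measured under the scaling as deposited. With the rescaled totals a median of 0.373 remained, so there the fast fibre share did not account for the whole shift. The real split called 2860 raised and 1177 lowered genes, 4037 in all, and 1 of the 10 splits of the 6 libraries, the real one, gave as many, the highest other value being 3 genes, but 10 splits are too few for a share under 0.05.

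Fast fibre and glycolysis genes were lower, at medians of -1.36 and -0.78. RNA of other cells that dilutes muscle RNA would lower all muscle genes alike, but 30 genes shared by fast and slow fibres had a median of -0.0117 (SD 0.572), away from the fast fibre median by more than their spread. Their median was -0.216 under median-of-ratios scaling (7 raised, 15 lowered) and 0.105 under quantile normalization (8 raised, 4 lowered). As reported it lay below the 0.21 of all tested genes, so a smaller dilution is not excluded. The 30 include Pgam2 (log2 -1.10), also a glycolysis gene. Median-of-ratios scaling gave a fast fibre median of -1.56 (camera adjusted p = 1.04e-11). It moved the typical gene down and could only deepen the fall, so it does not decide on scaling. Quantile normalization gave smaller falls, with a fast fibre median of -1.02 (12 lowered, 2 raised, camera adjusted p = 1.70e-04). The glycolysis median was -0.56 (13 lowered, 6 raised, camera adjusted p = 0.00274). Both lists stayed called downward, which argues against scaling as the only cause. For lists, the real split called 12 and the highest other split 7, and the 10 splits are again too few for a share under 0.05.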
